A study of Mus musculus with 5 samples.

How the data were processed

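Total RNA of the nucleus accumbens was extracted with the PicoPure kit and 50 ng of each sample was amplified linearly and labelled with Cy5 or Cy3, per the labels' protocols. The arrays were Agilent whole mouse genome arrays of long oligonucleotides, with 1 cocaine-treated and 1 saline-treated mouse on each. Per the submitters' processing notes the images were read with Agilent Feature Extraction, whose version, background correction and normalization are not given in the sources used here. The analysis started from the value table of the series, in which the deposited values are log2 ratios of the 2 channels.

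What the values hold was worked out from the table itself. In 3 columns written with 15 digits, 2 to the power of the value was a fraction of whole scanner counts or steps of 0.5. This held for 99.99% of the spots (relative tolerance 2e-14), so these values are log2 ratios of signals with no centring. A background subtracted in whole counts or steps of 0.5 would leave such fractions too, so they do not settle whether background was subtracted. The other 2 columns, those of the cocaine-in-Cy3 arrays, held 6 digits and were not tested this way. Array medians lay between -0.69 and 0.60. The log base is thereby settled for the 3 columns with 15 digits, and the other 2 were taken to share it. The direction was settled only as a likely reading, by a rule set before the data were examined. The rule took 239 features without a gene and among the 1% with the largest mean absolute ratio. Of these, 185 switched sign exactly with the dye orientation and 0 kept 1 sign on all 5 arrays. Control spots with a ratio fixed by the dye would do so only if the depositors had already turned the dye-swapped arrays. Whether these features are such control spots was not checked. All 5 arrays were thus read as running the same way, with the mean of the fit as the treatment coefficient and the orientation as the dye coefficient. The reading planned as the main one, Cy5 over Cy3 on every array, became the alternative. Which treatment is the numerator stays unknown. The 500 features at exactly 0 on all 5 arrays, none with a gene, were left out, which leaves 43790. There were 0 missing values.

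Features were named through the platform annotation given with the series, of which 32042 had 1 gene symbol, 47 had several and 12201 had none there. Of the first, 31906 had a gene identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed by it. No gene was named from a feature with several symbols.

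The treatment was tested per feature with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, treatment mean plus dye orientation, 3 residual degrees of freedom, Benjamini-Hochberg adjustment over all features, threshold 0.05). The 3 cocaine-in-Cy5 arrays alone were tested against 0 in the same way, without a dye term. Gene-level values were means over the features of a gene. The 30 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01, lists of at least 5 measured genes, Benjamini-Hochberg over the lists). An estimated correlation, and fry, which asks whether a list's genes move one way without reference to other genes, served as alternatives. Genes named in the text followed a rule set at the same time: up to 10 per side that pass the threshold with 1 sign on all 5 arrays, filled by smallest p where fewer pass, the 2 members of each list with the smallest p, and 12 genes chosen in advance. No gene passed the threshold, so all names of the first kind are fillers, and the numerator side had no candidate. With 5 arrays, the smallest 2-sided p that turning the signs of whole arrays can give is 0.0625, so no exact test per gene could pass 0.05.

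Spot brightness, which the table does not give, was recovered after the data were seen. A ratio in lowest terms loses the common factor of its 2 signals, and the factor was weighed over the 3 arrays with exact fractions (chance of a step of 0.5 0.2, spread between arrays 0.25 on the log2 scale, lowest signal 35 counts), using Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3. Most features formed a background class near 56 and 84 counts in the recovered signals. A gene spot was called above background at a recovered log2 brightness over 7.5, because 26.1% of the features between 6.5 and 7.5 still had the ratios of background spots (within 2.5 median absolute deviations on all 5 arrays) against 0.2% of those between 7.5 and 8. The brightness trend of each array was removed with loess (span 0.3), over all spots or over the gene spots above background. Thresholds of 7 and 8, and a normexp background correction with offset 50 on the recovered signals, were run as alternatives. Several earlier versions of the recovery and of the threshold were also tried and replaced because they placed background spots among brighter ones. With all 5 arrays none of them called a feature. Some called a few features on the denominator side when cocaine-in-Cy5 replicate 3 was left out, which the final version did not.

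For a test of the sign of 1 array, control features were chosen again by the same rule on the other 4 arrays alone. Random lists matched on brightness were drawn 10000 times per list. The alternatives set before the data were examined were the other reading of the sign, no dye term, centring, scaling and quantile normalization of the arrays, array weights, a robust prior, other feature sets, gene-level means, averaging of the 2 arrays whose cocaine RNA labels differ by a suffix, other thresholds and leaving out each array in turn. The fit was tested on simulated data with the features' own spread (43790 features, 200 changed): with all 5 arrays it recovered 40.3% of the changes of 0.5, 71.6% of those of 1 and 80.3% of those of 2 on the log2 scale, and called 4 unchanged features. Most of these features are at background, where the spread is small. With the 200 changes placed in gene spots above background, it recovered 0%, 1.5% and 0%. The fit with the brightness trend removed, over these 3702 spots, recovered 56.7%, 94% and 98.5% and called 11 unchanged ones, in a simulation without the compression that background causes. Coordinates are not given, since the table names no genome build. Figures were drawn with Matplotlib 3.10.9.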

Results

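The nucleus accumbens is the ventral striatal region that receives dopamine from the midbrain and takes part in reward learning. RNA from it was compared between cocaine-treated and saline-treated male C57BL6 mice on 5 long-oligonucleotide arrays, each read in the dyes Cy5 and Cy3. The animals had gone through conditioned place preference, a procedure in which a drug is paired with one compartment of a cage and the later time spent there is scored. Cocaine was given at 15 mg/kg on days 2, 3 and 4, and the cocaine-treated mice were those that scored low for the preference. Each array held RNA of 1 cocaine-treated and 1 saline-treated mouse. Cocaine RNA was in Cy5 on 3 arrays and in Cy3 on 2. The design text calls the 5 comparisons independent, although 2 cocaine RNAs in Cy5 (replicates 1 and 2) carry labels that differ only by a suffix, so they could be from 1 animal. The value table held 44290 features, of which 32042 were paired with 1 gene symbol, for 19087 genes. Median deposited log2 ratios were -0.69, -0.57 and -0.52 on the cocaine-in-Cy5 arrays and 0.53 and 0.60 on the cocaine-in-Cy3 arrays. The number of arrays limits the precision of every ratio below.

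All 5 arrays were read as running the same way between the treatments, the likely reading by the rule above. Which treatment is the numerator of the deposited ratio is not stated. Ratios are therefore given as lying to the numerator or the denominator side, a negative log2 ratio being the denominator side. Cocaine over saline is how the design text words the comparison, and the values did not settle it.

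Of the 32042 features with 1 gene, 3702 (11.6%) were above the background level recovered from the values, for 3257 genes. Among the gene lists fixed before the data were examined, 70 of 73 oxidative phosphorylation genes and 67 of 71 cytosolic ribosomal protein genes had a spot above background, as did 24 of 34 proteasome subunits. So did 13 of 20 astrocyte markers, among them Slc1a2 and Slc1a3, the glial glutamate transporters, 13 of 25 synaptic vesicle genes and 9 of 17 GABA signalling genes. Medium spiny neurons, the projection neurons of the accumbens, were represented by 5 of 9 direct-pathway markers (Drd1, Tac1, Pdyn, Sfxn1 and Lypd1), 3 of 10 indirect-pathway markers (Drd2, Penk and Adk) and 7 of 22 markers shared by both types, among them Rgs9 and Pde10a. Markers of tissue next to the accumbens were seldom above background: 0 of 18 for choroid plexus and ependyma, 0 of 23 for septal, preoptic and hypothalamic neurons and 2 of 25 for meninges and fibroblasts (Vim and Ptgds). So were those of less common cells of the accumbens itself, with 1 of 23 for endothelium and pericytes (Flt1) and 2 of 22 for interneurons (Sst and Npy). Microglial markers gave 3 of 20, blood cell genes 3 of 14 (all globins), oligodendrocyte markers 6 of 20 and cortical glutamatergic markers 6 of 24. A spot below this level was not counted, which does not show that its transcript was absent. The level is strict: of the 5391 features with a log2 brightness between 6.5 and 7.5, 26.1% had the ratios of background spots. The counts above may therefore be too low.

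The comparison of cocaine-treated with saline-treated mice asked which accumbens transcripts differ in animals with low place preference after cocaine. No feature passed the threshold. With limma, 0 of 43790 features had an adjusted p under 0.05, the smallest adjusted p was 0.731, and 998 features (2.28%) had an unadjusted p under 0.05, 517 on the numerator side and 481 on the denominator side. This last count and its split depended on the treatment of the arrays, while 0 features passed in each case: 10263 (66 and 10197) after quantile normalization, 7456 (2212 and 5244) with array weights, and from 240 to 2437 with 1 array left out. For the 3702 gene spots above background the median standard error was 0.30 on the log2 scale, and 742 of them (20%) had a 95% interval that stayed within 2-fold. In simulated data this fit found 1 of 200 changes of 0.5 to 2 on the log2 scale placed in such spots, so its count of 0 says little about them. Most of that error was a trend of the ratio with spot brightness that differed between arrays. With this trend removed from each array, a step chosen after the data were seen, the median standard error over the same spots was 0.10, and 3694 of the 3702 (99.8%) had an interval within 2-fold, with 0 past the threshold, a smallest adjusted p of 0.644 and 249 at an unadjusted p under 0.05. In simulated data that fit found 56.7% of changes of 0.5, 94% of those of 1 and 98.5% of those of 2 on the log2 scale. There 200 of the 3702 spots were changed, and 11 unchanged ones were called. The simulation left out the compression that background causes, and a smaller number of changed spots was not simulated. These shares may therefore not hold for the real data. Whether background was subtracted from the deposited signals could not be settled. If it was not, the ratios understate the change of dim spots.

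Genes to name were taken from features with 1 sign on all 5 arrays, which lay on the denominator side alone. The dye offset gives dim spots opposite signs in the 2 orientations, so this rule passes over spots that keep that offset, whatever their p. Of features with a usable gene symbol, 0 were on the numerator side of all 5 arrays and 569 were on the denominator side of all 5, 35.3% of which were above background. Cocaine-in-Cy5 replicate 1 had a negative median ratio in every brightness class (-0.65 to -1.77), which left little room for the numerator side. The 1-sided count therefore shows no shared direction of change. The 10 with the smallest p among the 569, none past the threshold (adjusted p 0.731 each), began with Syt1, the calcium sensor of synaptic vesicle release, at -0.22 ± 0.05 (SE). They also held Atp2c1, a Golgi calcium and manganese pump, at -0.58 ± 0.15, Hbb-bt, an adult beta globin, at -0.65 ± 0.18, and Lsm14b, an RNA-binding protein, at -0.43 ± 0.10. Vwf, the endothelial clotting factor, stood at -0.39 ± 0.11, and the epidermal growth factor receptor Egfr at -0.38 ± 0.11. Eif2s2, a subunit of a translation initiation factor, stood at -0.36 ± 0.10, Ikbkg, the regulatory subunit of the NF-kappaB kinase, at -0.35 ± 0.09, the deubiquitinase Usp15 at -0.35 ± 0.10 and the steroid-synthesis enzyme Cyp17a1 at -0.26 ± 0.07. Each of these values is that of 1 spot and not of the gene. All of the genes but Cyp17a1 had other spots, from 1 for Lsm14b to 6 for Usp15, which do not enter it. Of these 10 spots only that of Syt1 was above background, and its log2 ratio became 0.21 ± 0.21 once the brightness trend was removed.

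The 12 genes chosen in advance for cocaine and for medium spiny neurons gave no ratio past the threshold. Among immediate early genes, Egr1 stood at -0.57 ± 0.37 (adjusted p 0.731) and Arc, a synaptic plasticity gene, at -0.43 ± 0.34 (adjusted p 0.731). The dopamine receptor spots above background gave -0.24 ± 0.36 for Drd1 (adjusted p 0.831) and -0.37 ± 0.33 for Drd2 (adjusted p 0.737). The opioid peptide precursors stood at -0.71 ± 0.47 and -0.68 ± 0.57 for the spots of Penk and at -0.69 ± 0.43 for Pdyn. Tac1, the substance P precursor, had 1 spot above background at -0.36 ± 0.40, and Cartpt, a neuropeptide precursor first described as regulated by cocaine and amphetamine, had 2 at -0.49 ± 0.34 and -0.54 ± 0.33. With the brightness trend removed, Egr1 stood at 0.01 ± 0.13, Arc at 0.13 ± 0.12, Pdyn at -0.07 ± 0.12, Drd2 at -0.01 ± 0.11 and Tac1 at 0.23 ± 0.09 (adjusted p 0.644). Cartpt stood at 0.04 ± 0.11 and -0.08 ± 0.12 for its 2 spots, and Drd1 at 0.32 ± 0.10, on the numerator side of 5 of 5 arrays, with an adjusted p of 0.644. The trend-removed spots of Penk gave -0.02 ± 0.14 and -0.12 ± 0.22. Spots of Fos, Bdnf and Homer1 and the spot of Ppp1r1b, the DARPP phosphoprotein of dopamine signalling, were not over the brightness threshold of 7.5. The spot of Ppp1r1b (brightness 7.45, ratio -0.06 ± 0.33) and a spot of Homer1 (7.1, -0.26 ± 0.22) were over the alternative threshold of 7.

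**Figure D1:**
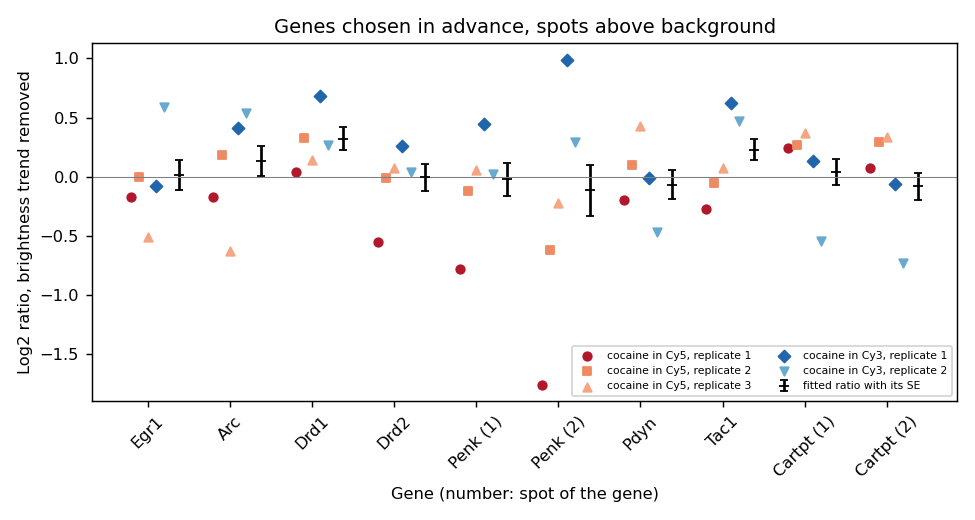
Log2 ratio with the brightness trend removed (y axis) for each spot above background of the genes chosen in advance (x axis), 1 symbol per array, with the fitted ratio and its standard error in black. Drd1, at 0.32 ± 0.10, was the spot whose 5 arrays all lay on the numerator side, and the others had arrays on both sides of 0.

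The 4 lists of broadly expressed genes that passed the threshold lay to the denominator side of the other genes as deposited. All 4 calls ended with an estimated correlation (camera, adjusted p = 0.986 for each) and when the brightness trend was removed. With the estimated correlation the adjusted p was 0.986 for all 30 lists, so here and below that value told no list from another. Its smallest unadjusted p was 0.347 (camera, oxidative phosphorylation), so no list came near a call. The small p values below thus rest on the preset correlation of 0.01. In fry each of the 4 lists had an adjusted p of 0.612. The 73 oxidative phosphorylation genes had a median log2 ratio of -0.53 (camera, adjusted p 4.51e-11), with 73 of 73 on the denominator side, among them Cox7a2 at -0.74 ± 0.27 and Ndufa5 at -0.68 ± 0.26. The 71 ribosomal protein genes had a median of -0.50 (adjusted p 4.81e-10), with 70 of 71 on that side, such as Rpl34 at -0.79 ± 0.30 and Rpl38 at -0.45 ± 0.17. The 34 proteasome subunits stood at -0.28 (adjusted p 0.0117), with 34 of 34 on that side, such as Psma7 at -0.56 ± 0.24 and Psmb3 at -0.47 ± 0.22. The 28 heat shock and unfolded protein response genes stood at -0.26 (adjusted p 0.0029), with 28 of 28 on that side, such as the chaperones Dnajb1 at -0.50 ± 0.22 and Hsp90aa1 at -0.85 ± 0.38. The median over all genes was -0.04. Lists that were not called also had most members on that side. They ranged from 10 of 18 choroid plexus and ependyma markers to 10 of 10 opioid and cannabinoid receptors. The counts of members per side thus do not set the 4 lists apart. No member of these lists passed the threshold, either over all genes or adjusted over the list alone.

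Over spots above background without the trend, the medians were 0.04 for oxidative phosphorylation (adjusted p 0.353), 0.03 for ribosomal proteins (adjusted p 0.353), 0.09 for proteasome subunits (adjusted p 0.0964) and -0.05 for the heat shock list (adjusted p 0.353). Random lists of genes as bright as the members had medians of -0.54, -0.55, -0.30 and -0.25 in the same order. The ribosomal list stood at percentile 99 of its random lists, less far to the denominator side than genes as bright, and the others at 80.7, 69.1 and 40. Without cocaine-in-Cy5 replicate 1, the deposited medians of oxidative phosphorylation and ribosomal protein genes were -0.29 and -0.23, that of the heat shock list -0.09 (adjusted p 0.0159) and that of proteasome subunits -0.07, no longer past the threshold (adjusted p 0.288).

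**Figure D2:**
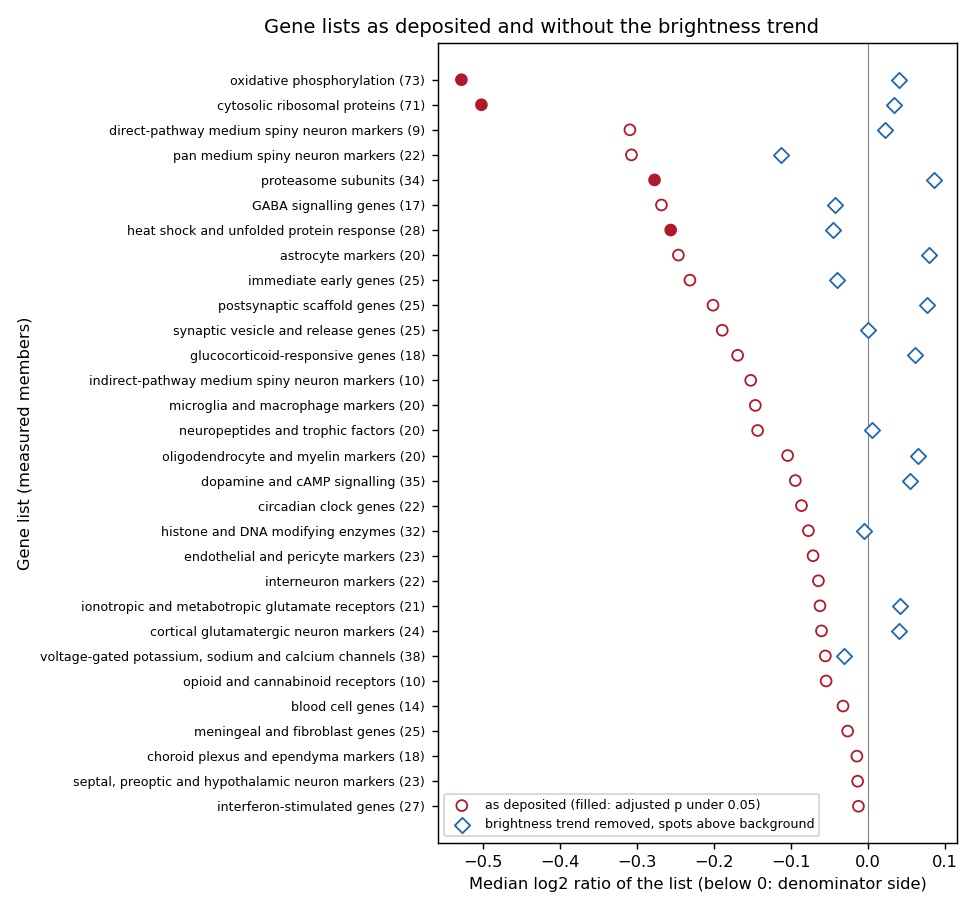
Median log2 ratio (x axis) of the 30 gene lists (y axis, with the number of measured members) as deposited, in circles filled where the camera adjusted p was under 0.05, and with the brightness trend removed over spots above background, in diamonds for the 19 lists with at least 5 such genes. The oxidative phosphorylation list moved from -0.53 to 0.04.

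The lists closest to the treatment and to the projection neurons did not pass the threshold in the fit to all 5 arrays with a dye term, but some did in other settings at the preset correlation, before the trend was removed. Immediate early genes passed on the denominator side after median-centring (adjusted p 0.0343), without a dye term (8.84e-05) and without cocaine-in-Cy3 replicate 2 (0.0142) or cocaine-in-Cy5 replicate 2 (0.00225), but not with an estimated correlation (0.986). Markers of both medium spiny neuron types passed on that side after median-centring (0.0343), without a dye term (4.39e-07) and without cocaine-in-Cy3 replicate 1 (0.0237) or cocaine-in-Cy5 replicates 2 (0.0149) or 3 (0.0294), but not with an estimated correlation (0.986). Without cocaine-in-Cy5 replicate 1 neither passed, and their medians were -0.07 and -0.10, and without cocaine-in-Cy3 replicate 1 the immediate early median was -0.09 (adjusted p 0.191). Direct-pathway and indirect-pathway markers, dopamine signalling and neuropeptides passed on the denominator side without a dye term alone, and had an adjusted p of 0.986 with an estimated correlation. Under the other reading of the sign, in which the dye coefficient is the treatment, these lists except the indirect-pathway markers passed toward the numerator side of the other genes, with medians still below 0 (-0.34, -0.29, -0.15, -0.45 and -0.40, against -0.55 for all genes; adjusted p 0.0015 for immediate early genes, 2.9e-06 for markers of both types, 0.000615 for direct-pathway markers, 0.000871 for dopamine signalling and 0.00229 for neuropeptides). Postsynaptic, vesicle, GABA, glucocorticoid and astrocyte lists, described below, also passed in that direction under it, with medians from -0.44 to -0.31 (0.00077, 0.000954, 0.00148, 0.00903 and 3.58e-05). Immediate early genes had a median of -0.23 over 25 genes (adjusted p 0.0532), with 23 of 25 on the denominator side, among them Klf2 at -0.88 ± 0.40 and Ier2 at -0.08 ± 0.04. Without the trend the 9 immediate early genes above background stood at -0.04 (adjusted p 0.467), of which Nr4a1 was at -0.04 and Junb at 0.22. Direct-pathway markers stood at -0.31 over 9 genes (adjusted p 0.145), including Slc35d3 at -0.43 ± 0.21 and Sfxn1 at -0.31 ± 0.18. Indirect-pathway markers stood at -0.15 over 10 genes (adjusted p 0.285), including Upb1 at -0.41 ± 0.22 and Adk at -0.47 ± 0.27. Markers of both types stood at -0.31 over 22 genes (adjusted p 0.0596), including Rxrg at -0.66 ± 0.40 and Arpp21 at -0.37 ± 0.22. Dopamine and cAMP signalling stood at -0.09 over 35 genes (adjusted p 0.538), including Maob, a dopamine-degrading oxidase, at -0.51 ± 0.17 and Prkaca, the protein kinase A catalytic subunit, at -0.53 ± 0.27. Without the trend its 15 genes above background stood at 0.06 (adjusted p 0.353). Neuropeptides and trophic factors stood at -0.14 over 20 genes (adjusted p 0.376), with Adcyap1 at 0.09 ± 0.04 and Pomc at -0.17 ± 0.10. Opioid and cannabinoid receptors, of which 1 was above background, stood at -0.05 over 10 genes (adjusted p 0.647), with the endocannabinoid-synthesis genes Daglb at -0.31 ± 0.18 and Dagla at -0.23 ± 0.16.

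Synaptic and channel genes did not pass in that fit either. Without a dye term postsynaptic, vesicle and GABA genes did (adjusted p 0.0234, 0.00882 and 0.00139), as did vesicle genes without cocaine-in-Cy5 replicate 2 (0.0174), and none of these with an estimated correlation (0.986 for each). Without cocaine-in-Cy5 replicate 1 their medians shrank to -0.06, -0.04 and -0.09, with none past the threshold. Glutamate receptors stood at -0.06 over 21 genes (adjusted p 0.647), with Grin2d at -0.78 ± 0.23 and Grik4 at -0.40 ± 0.18. Postsynaptic scaffold genes stood at -0.20 over 25 genes (adjusted p 0.145), with Camk2a at -0.16 ± 0.07 and Nlgn3 at -0.37 ± 0.20. Synaptic vesicle genes stood at -0.19 over 25 genes (adjusted p 0.145), with Pclo at -0.40 ± 0.15 and Syn1 at -0.56 ± 0.27. GABA signalling genes stood at -0.27 over 17 genes (adjusted p 0.127), with Gabra2 at -0.30 ± 0.12 and the receptor anchor Gphn at -0.14 ± 0.06. Voltage-gated channels stood at -0.06 over 38 genes (adjusted p 0.565), with Cacng3 at -0.12 ± 0.06 and Kcnq5 at -0.12 ± 0.06.

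Regulatory lists behaved alike. Histone and DNA modifying enzymes stood at -0.08 over 32 genes (adjusted p 0.288), with the histone methyltransferase Ehmt1 at -0.55 ± 0.24 and the deacetylase Hdac1 at -0.27 ± 0.13. Glucocorticoid-responsive genes stood at -0.17 over 18 genes (adjusted p 0.145), with Sult1a1 at -0.34 ± 0.12 and Pdk4 at -0.22 ± 0.08, and passed without cocaine-in-Cy5 replicate 3 (adjusted p 0.0495) but not with an estimated correlation (0.986). Clock genes stood at -0.09 over 22 genes (adjusted p 0.647), with Nfil3 at -0.12 ± 0.07 and Hlf at -0.46 ± 0.30. Interferon-stimulated genes, of which 1 was above background, stood at -0.01 over 27 genes (adjusted p 0.738), with Ifitm3 at -0.58 ± 0.26 and Oas1b at 0.08 ± 0.04.

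No marker list of another cell type or tissue passed in the fit to all 5 arrays with a dye term. Astrocyte markers passed on the denominator side after median-centring (adjusted p 0.0343), without a dye term (9.43e-05) and without cocaine-in-Cy5 replicates 2 (0.0205) or 3 (0.0372), but not with an estimated correlation (0.986), and had a median of -0.09 without replicate 1. Cortical glutamatergic markers passed on the numerator side without cocaine-in-Cy3 replicate 1 (0.0444) and on the denominator side without replicate 2 (0.0428), and not with an estimated correlation (0.986). Astrocyte markers stood at -0.25 over 20 genes (adjusted p 0.0596), with Sparcl1 at -0.88 ± 0.40 and Glul at -0.29 ± 0.15, and at 0.08 over 13 genes without the trend (adjusted p 0.353). Oligodendrocyte markers stood at -0.10 over 20 genes (adjusted p 0.934), with Olig2 at 0.06 ± 0.04 and Olig1 at -0.29 ± 0.19. Microglial markers stood at -0.15 over 20 genes (adjusted p 0.145), with Tyrobp at -0.27 ± 0.12 and Ctss at -0.74 ± 0.37. Endothelial and pericyte markers stood at -0.07 over 23 genes (adjusted p 0.162), with Esam at -0.20 ± 0.05 and Kcnj8 at -0.22 ± 0.08. Only 1 of these 23 genes was above background. The medians of choroid plexus (18 genes), septal to hypothalamic (23), meningeal (25) and blood cell genes (14) were -0.01, -0.01, -0.03 and -0.03, with adjusted p of 0.821, 0.565, 0.647 and 0.927. In the same order 0, 0, 2 and 3 genes of these lists were above background. Their medians near 0 are thus mostly ratios of background spots and say little about these cells. Members of these lists with the smallest p included Dynlrb2 at -0.11 ± 0.06, Clic6 at -0.27 ± 0.17, Avp at 0.12 ± 0.04, Nr5a1 at -0.22 ± 0.10, Mgp at -0.27 ± 0.13, Aldh1a2 at -0.09 ± 0.05, Hbb-bt at -0.52 ± 0.16 and Pf4 at -0.11 ± 0.06. Cortical glutamatergic markers stood at -0.06 over 24 genes (adjusted p 0.956), with Lhx2 at -0.42 ± 0.21 and Fezf2 at 0.08 ± 0.04, and interneuron markers at -0.06 over 22 genes (adjusted p 0.811), with Htr3a at -0.15 ± 0.06 and Nos1 at -0.29 ± 0.15. For the interferon, choroid plexus, septal and meningeal lists the median was below 0 while the test, which compares a list with the other genes, pointed to the numerator side. Every list member named here had an adjusted p of 0.713 over all genes.

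Far more features depended on the dye than on the treatment, mostly at background. In the same limma fit 34346 of 43790 features depended on the dye orientation at adjusted p under 0.05, 184 with a positive and 34162 with a negative coefficient, the sign being that of the cocaine-in-Cy5 arrays. Over the 3 cocaine-in-Cy5 arrays alone, 33630 features differed from a ratio of 1 (180 on the numerator and 33450 on the denominator side, median log2 ratio -0.60). With each array centred on its median, 0 features did, with 488 at an unadjusted p under 0.05. Among abundant genes the median dye coefficient was 0.07 for oxidative phosphorylation and 0.01 for ribosomal proteins, but these small values average unlike arrays. Between a log2 brightness of 9 and 10 the median ratio was -1.77, -0.15 and 0.25 on the cocaine-in-Cy5 arrays and -0.88 and -0.27 on the cocaine-in-Cy3 arrays. Cocaine-in-Cy5 replicates 2 and 3 thus lay above both cocaine-in-Cy3 arrays, and replicate 1 below them. Over the 3702 gene spots above background 0 passed for the dye, with the brightness trend left in or removed, which shows no call rather than no difference. Spots at background carried the offset. For spots below the median brightness, signals were computed from the recovered brightness and the ratios of cocaine-in-Cy5 replicate 1. They had medians of 55.8 and 84.0 counts in its numerator and denominator channels. The brightness was weighed over 3 arrays, so these are not counts read on this array. On the cocaine-in-Cy3 arrays the median ratio of such spots had the opposite sign (0.60 and 0.67 on the log2 scale).

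The ratio also changed with brightness in a way particular to each array. From the 33866 features up to a log2 brightness of 6.5 to the 844 between 9 and 10, the median ratio moved from -0.65 to -1.77 on cocaine-in-Cy5 replicate 1, but from -0.61 to -0.15 and from -0.56 to 0.25 on replicates 2 and 3. In the 226 brightest features, over a log2 brightness of 12, these 3 arrays stood at -1.25, 0.10 and 0.50. On the cocaine-in-Cy3 arrays it moved from 0.58 to -0.88 and from 0.64 to -0.27. The fitted ratio, with the dye term taken out, moved from 0 to -0.56 over the same range.

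**Figure D3:**
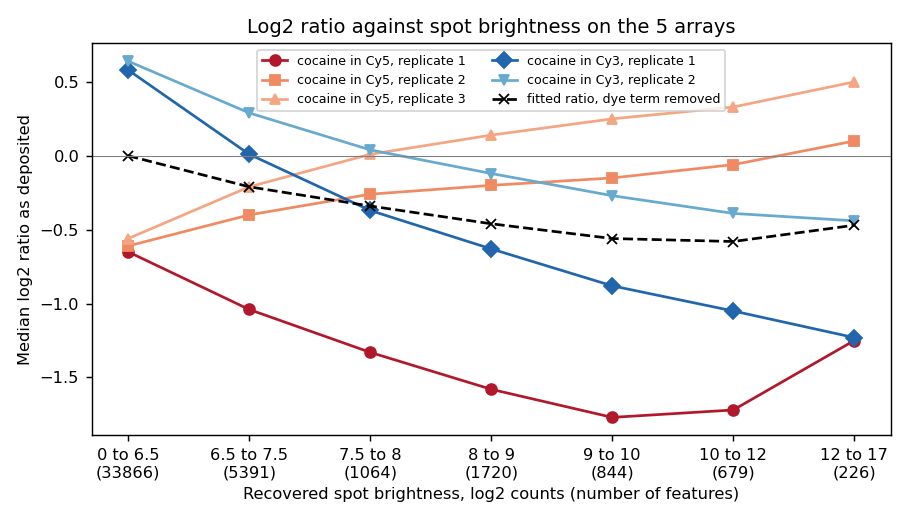
Median deposited log2 ratio (y axis) in 7 classes of recovered spot brightness (x axis, log2 counts, with the number of features) for each of the 5 arrays, and the median fitted ratio with the dye term removed (dashed). Cocaine-in-Cy5 replicate 1 goes down with brightness to -1.77 between 9 and 10 and back to -1.25 in the brightest class, while the other 2 of its orientation go up.

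Agreement between arrays, taken across features, which are not independent replicates, followed the dye orientation except on that array. The mean Pearson correlation was 0.33 (SD 0.60) over the 4 pairs of one orientation and -0.40 (SD 0.64) over the 6 pairs of opposite orientation. These means were 0.11 and -0.29 by Spearman correlation and 0.07 and -0.29 over features with 1 gene, where cocaine-in-Cy5 replicate 1 stood at 0.76 and 0.73 with the cocaine-in-Cy3 arrays. Over all features, cocaine-in-Cy5 replicates 2 and 3 correlated at 0.80 and the 2 cocaine-in-Cy3 arrays at 0.89. Cocaine-in-Cy5 replicate 1 correlated at -0.03 and -0.32 with the others of its orientation and at 0.47 and 0.38 with the cocaine-in-Cy3 arrays. Without the brightness trend and over spots above background these 4 values were 0.13, -0.13, -0.11 and 0.05. The other pairs still followed the orientation there, at 0.55 and 0.32 within it and at -0.17, -0.34, -0.36 and -0.73 between, for means of 0.22 and -0.28 over all pairs.

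**Figure D4:**
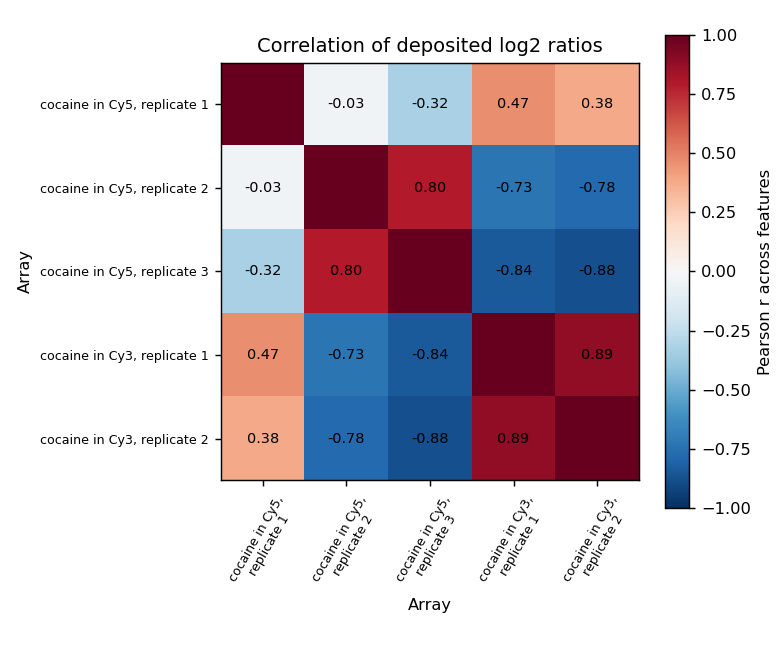
Pearson correlation across 43790 features of the deposited log2 ratios for each pair of the 5 arrays (both axes), with the value of r in each cell. The cocaine-in-Cy5 replicate 1 array stands at 0.47 and 0.38 with the cocaine-in-Cy3 arrays and at -0.03 and -0.32 with its own orientation.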

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

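The tests of the array that stands apart, the random lists of equal brightness and the removal of the brightness trend were chosen only after the results were seen. For the gene lists, what each explanation would give was written down before that test was run.

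The treatment ratio differed between the dye orientations for 34346 of 43790 features (limma, adjusted p under 0.05), 34162 of them with lower values on the cocaine-in-Cy5 arrays. Over the 3702 gene spots above background 0 passed with the trend left in, and 0 with it removed, which shows no call rather than no difference, since the correlations between arrays still followed the orientation. With the trend removed over all 43790 features 0 passed as well, since that step also takes out the offset of each array.

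A signal appeared in features that carry no gene, which were fitted with the others but enter no result on genes. Of 239 such features with large ratios, 185 switched sign exactly with the dye orientation. The 150 of these that were positive on the cocaine-in-Cy5 arrays had median log2 ratios of 2.67, 2.38 and 2.16 on those arrays and of -1.84 and -1.69 on the cocaine-in-Cy3 arrays.

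The 4 gene lists that lay to the denominator side of the other genes are lists of widely expressed genes, and their shift may reflect an imbalance of the channels that depends on brightness. After each array's brightness trend was removed, 0 of the 4 lists stayed past the threshold on their side, and the median of oxidative phosphorylation went from -0.53 to 0.02 over all spots. Genes as bright as the members had medians whose 95% range held 3 of the lists (for oxidative phosphorylation -0.58 to -0.50), while the ribosomal list (-0.50) lay outside its range of -0.58 to -0.51, nearer to 0. A single array is argued against as the whole cause, since 3 of the 4 lists stayed past the threshold (at the preset correlation) without cocaine-in-Cy5 replicate 1, although medians shrank to -0.29 (oxidative phosphorylation), -0.23 (ribosomal proteins) and -0.09 (heat shock) and the proteasome call was lost (median -0.07, adjusted p 0.288). An effect of cocaine on abundant transcripts as a class would follow brightness too and stays open, untested.

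Cocaine-in-Cy5 replicate 1 correlated better with the dye-swapped arrays than with its own orientation. A wrong sign of the deposited ratio for this array is argued against: of 258 control features chosen on the other 4 arrays alone, 94.2% carried the sign of its own orientation on this array. These features follow the dye, so they cannot show whether the 2 RNAs were exchanged on this array, which was not tested. A candidate explanation is less labelled RNA in the numerator channel of this array relative to the control spots. Its bright gene spots lay 4.46 log2 units below the dye-fixed control spots, against 2.49 and 1.87 on the other arrays of its orientation, a gap larger by 1.97. Most of that gap is the median ratio of the gene spots themselves (-1.788, against -0.107 and 0.285). It therefore restates the pattern and is no separate test of the explanation. A gap between log ratios cannot tell less RNA in the numerator channel from more in the denominator channel. Whether the gap came from the amount of RNA, its quality or the labelling was not tested, and a difference between the animals stays open.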

How the results depend on the processing

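Loess, normexp and the brightness thresholds were chosen after the data were seen; the other settings were not. The count of 0 features for the treatment (limma, 998 at an unadjusted p under 0.05) was 0 under all alternatives except 2: 34346 under the other reading of the sign, where the dye coefficient takes its place, and 35 at an unadjusted p under 0.01. Leaving out each array in turn gave 0, also with loess or normexp. The smallest adjusted p ranged from 0.106 (loess, spots above background, without cocaine-in-Cy5 replicate 3) to 0.991, the other reading aside, and was 0.177 without the dye term. Quantile normalization and no dye term moved the median of all features to -0.16 and -0.14.

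The count for the cocaine-in-Cy5 arrays alone ranged from 25113 to 37737 with an array left out and was 0 after median-centring. The dye effect was past the threshold for 123 features after median-centring and for 0 with loess over all spots, with loess over spots above background and over these spots with the trend left in.

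Of 30 lists, 4 passed as deposited, 14 with no dye term, 7 after median-centring (all on the denominator side) and 14 under the other reading (all toward the numerator side of an all-gene median of -0.547). With an estimated correlation, with fry, and with loess or normexp, 0 passed. With 1 array left out, counts ranged from 0 to 8. As deposited they were 3 without cocaine-in-Cy5 replicate 1, 8 and 7 without replicates 2 and 3, and 6 without each of the cocaine-in-Cy3 arrays. With loess 3 passed without cocaine-in-Cy3 replicate 1 (GABA signalling on the denominator side, oxidative phosphorylation and proteasome on the numerator side) and 0 in the other cases.

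Directions of the 4 lists turned. Under the other reading their tests pointed to the numerator side, with medians of 0.073 (oxidative phosphorylation), 0.007 (ribosomal proteins), -0.343 (proteasome) and -0.367 (heat shock). With loess over all spots the first 3 stood at 0.015, 0.033 and 0.020, over spots above background, also with an estimated correlation, at 0.041, 0.034 and 0.086, and with normexp at 0.042, 0.034 and 0.087. Over all fits with 1 array left out, medians ranged from -0.711 to 0.078, -0.668 to 0.043, -0.405 to 0.136 and, for heat shock, -0.342 to 0.051. Of 177 values of the 10 genes named by smallest p, 161 kept their side and 16 turned. These genes were chosen for 1 sign on every array. Fits that only weight, average or leave out arrays of the deposited values therefore could not turn them. Of the 10 spots, only that of Syt1 entered the loess and normexp fits over spots above background. The 161 is thus largely set by the choice of genes and does not show a stable direction. Under the other reading Syt1 stood at 0.082, Lsm14b at 0.177 and Hbb-bt at 0.154. With loess Syt1 stood at 0.162 over all spots, 0.213 above background, 0.209 and 0.213 at thresholds of 7 and 8 and 0.216 with normexp. With 1 array left out it ranged from -0.252 as deposited (without cocaine-in-Cy5 replicate 2) to 0.388 with normexp, and with loess or normexp alone from -0.011. Beyond the brightness trend that loess removes, the cause was not tested.

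With the 2 similarly labelled cocaine RNAs as a block, the correlation within the block could not be estimated, so that fit was not run. No value was missing, so allowing a missing array changed nothing. No other log base was run, since the fractions settle it. Signal limits these results: 11.6% of gene features were above background.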

Other observations

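The genes below were named after their values were seen. With the brightness trend removed, the gene spots above background with the smallest p, none past the threshold (adjusted p 0.644 each), were led by Ensa, an inhibitor of a protein phosphatase, at 0.55 ± 0.10 (SE) on the numerator side of 4 of 5 arrays. Rusc1 stood at -0.66 ± 0.14, on the denominator side of 4 of 5 arrays. The transcription factor Klf2 stood at -0.83 ± 0.18 at this spot, and at -0.34 ± 0.10 as a mean over its spots. The linker histone H1f10, at -0.60 ± 0.14, and the chaperone Dnajb1, at -0.35 ± 0.09, were on the denominator side of 5 of 5 arrays, as was Efcab14 at -0.27 ± 0.08. Trim37 and Sowaha, at 0.40 ± 0.11 and 0.33 ± 0.10, were on the numerator side of 5 of 5.

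Proteasome subunits were the list nearest to a call once the trend was removed over spots above background, with 20 of 24 genes on the numerator side (median 0.09, adjusted p 0.0964), led by Psmc5 at 0.36 ± 0.11. With an estimated correlation the list's adjusted p in camera was 0.787, a value most lists shared. With 1 array left out the list's median ranged from 0.036 to 0.136. Over all spots it stood at an adjusted p of 0.555, and heat shock (0.141) and ribosomal proteins (0.142) were nearer. As deposited, 34 of 34 proteasome genes lay on the denominator side.

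For 363 genes with at least 2 spots above background, the first 2 spots of a gene correlated across genes at 0.43, 0.42 and 0.62 on the cocaine-in-Cy5 arrays and at 0.28 and 0.48 on the cocaine-in-Cy3 arrays, without the brightness trend. Their treatment coefficients correlated at 0.10, with the same sign for 59.0% of the genes.

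The labels give all animals as male. Spots of the X-inactivation transcript Xist and of the Y-linked genes Eif2s3y, Kdm5d and Uty were all below the brightness threshold, so the sex of the samples could not be checked.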
